A study of Oryza sativa with 16 samples.

How the data were processed

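Gene expression was measured in rice (Oryza sativa ssp. japonica, cultivar Nipponbare) on 16 Agilent 2-colour arrays. Embryoless half-seeds, which keep the endosperm and its aleurone layer, of the wild type (WT) and of the mutants gid1, gid2 and slr1 were kept for 36 h at 30 °C in a medium of 10 mM acetate at pH 5.2 with 2 mM CaCl2, either with 10 µM gibberellic acid (GA3, here GA) or without it (mock). Each array carried GA and mock RNA of 1 genotype in its 2 channels. Each genotype had 4 arrays, which the labels number as 2 replicates, and each replicate number was hybridised in both dye orientations.

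Per the file headers, each scanner file holds the mean signal intensity and the median local background intensity of 45151 spots in both channels, with no normalisation applied to them. Per the file headers, the scanner software was Agilent Feature Extraction, version 9.5.3.1 for the arrays labelled WT, gid1 and gid2 and version 10.5.1.1 for those labelled slr1. A further pair of columns holds the software's processed intensity, which per the file headers was background-subtracted, detrended and dye-normalised by LOWESS within the array. The authors' deposited value table of the whole series holds log2 ratios normalised by variance stabilisation (VSN), per the labels of the series; its software version is not given in the sources used here. All 16 of its columns run as GA over mock, and their slopes on the scanner ratios lay between 0.730 and 0.978. What sets its centring is unknown: column medians were 0.02 to 0.04 for WT, 0.00 to 0.03 for gid2, −0.29 to 0.37 for the columns labelled gid1 and −0.01 to 0.02 for those labelled slr1.

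The value table and the scanner files conflict for 2 of the 4 genotypes. Columns labelled WT correlated with their own scanner files at r of 0.9987 to 0.9990 across the 22105 probes well above background everywhere, and columns labelled gid2 at 0.990 to 0.995. Columns labelled gid1 followed the scanner files labelled slr1 (r 0.894 to 0.915, against 0.0254 to 0.285 for their own), and columns labelled slr1 followed the scanner files labelled gid1 (r 0.987 to 0.992, against 0.0832 to 0.285). Replicate number and dye matched in all 16. The match was tried on several scanner scales and probe sets, and the exchange appeared in each; the reported scale is one with the highest correlations. Groups were taken from the labels of the scanner files, and "labelled gid1" and "labelled slr1" are written throughout.

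From the intensities, background was subtracted with normexp (offset 50), log2 ratios were normalised by loess within each array with control spots at weight 0, and every ratio was turned to GA over mock. The 2 arrays of 1 replicate number, of opposite dye, were averaged, so that dye effects cancel and each genotype has 2 replicates. The 8 replicate means entered 1 limma fit with a coefficient per genotype (4 residual and 2.59 prior degrees of freedom). Differences between genotypes were tested as contrasts of that fit. P values are 2-sided, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. No exact test on 2 replicates can pass that threshold, so limma's shared estimate of the spread was used. Each SE is therefore the moderated one of a fit over all 4 genotypes, and n counts the replicates averaged. The residual SD was 0.204 in WT, 0.346 on the arrays labelled gid1, 0.187 in gid2 and 0.194 on those labelled slr1. A shared estimate can thus be too small for gid1 and too large for the others. The labels do not say that replicates came from separate material, so p values measure only the spread between these samples. The number of arrays limits the precision.

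A probe was tested when it was well above background on all 4 arrays of at least 1 genotype and treatment. Of 41919 probes, 31599 passed, and the brightest probe of each locus represented 21856 genes. Of 6285 loci with more than 1 tested probe, 2 had probes a 2-fold apart in opposite directions in WT. Spots marked as outliers by the software were left out, which left 577 genes without a value in at least 1 replicate. Gene names are the array's own descriptions, which can be old: none of the array's loci was found among the 39387 entries of the reference table, and coordinates are not used here. The locus given for GID2 is described on the array as a 14-3-3-like protein, so it was left out of the signalling list, and its values are given with that limit.

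Untreated levels were compared with separate-channel log2 intensities after loess and Aquantile scaling between arrays, averaged over each dye pair. The 25 gene lists were tested with camera (preset correlation 0.01, and estimated) and with fry, adjusted over the lists of a contrast. camera compares a list with all other genes. fry's directional p asks whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction. The lists were alpha-amylases; other starch-degrading enzymes; cysteine proteinases; serine carboxypeptidases and aspartic proteinases; cell wall hydrolases and expansins. Others were secreted nucleases, fatty acid oxidation and the glyoxylate cycle, phosphatases and phosphate transporters, endoplasmic reticulum folding and secretion, aquaporins, sugar transporters, amino acid and peptide transporters, gibberellin metabolism, gibberellin signalling, late embryogenesis abundant (LEA) proteins and dehydrins, abscisic acid response, defence proteins, antioxidant enzymes and heat shock proteins. The remaining lists were cytosolic ribosomal proteins, core histones and cyclins, autophagy and vacuolar processing, and markers of starchy endosperm, of embryo and oil bodies, and of green tissue. They hold 869 tested genes, 1 of them in more than 1 list. Members whose description contradicts their list were left out, and a few of these exclusions, for isopropylmalate enzymes and spots without a described product, were made from the descriptions after called values had been seen.

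Named genes followed a rule. For WT these are the 10 largest rises and 10 largest falls among genes past the threshold, moved the same way on all 4 arrays and with an informative description, plus the 2 called members of each list with the lowest p. For each mutant and each difference from WT they are the 5 largest in each direction, and the loci of GID1, GID2, SLR1 and GAMYB are always named. Groups, tests, other settings to be tried, this rule and, apart from the exclusions named above, the lists were fixed before the data were examined. The other settings covered background correction, normalisation, the value table, the filter on dim probes, every probe on its own, arrays as separate samples, a replicate block, the moderation, the genotypes in the fit, a 2-fold minimum and each replicate left out. The main steps were tested on simulated data with 21279 genes, of which only 50 changed by each size, against 49.0% of genes called in the real WT data. Fewer changed genes make the adjusted threshold stricter. Noise between dye partners was also added to a spread that already held it. The simulated recovery is therefore not that of the real WT response. For the simulated WT response, 24% of changes of 0.5 on the log2 scale were recovered, 64% of changes of 1, 96% of changes of 2 and 100% of changes of 3. The simulated gid1 response gave 12%, 78%, 90% and 98%, that of gid2 28%, 68%, 88% and 98%, and that of slr1 22%, 68%, 94% and 96%. Every genotype was simulated with the same spread for each gene, the same changed genes and the same sizes. Differences between the simulated genotypes are therefore random draws and do not measure the power or error of a genotype. The larger spread of gid1 and the dimmer signal of slr1 were not simulated. Of the simulated calls 8.97% were false for WT, 5.44% for gid1, 7.84% for gid2 and 2.10% for slr1. For WT minus gid1, gid2 and slr1, 0% of changes of 0.5 and 26%, 40% and 42% of changes of 1 were recovered, and 0.962%, 7.69% and 4.31% of calls were false. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0 and the data.table package, version 1.17.8.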

Results

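The series addressed whether rice aleurone cells respond to gibberellin (GA) when the known receptor is missing. The aleurone, the outermost cell layer of the cereal endosperm, secretes hydrolases that mobilise the grain's reserves in response to GA. GID1 is the soluble GA receptor, SLR1 the DELLA protein that represses GA responses, and GID2 the F-box protein through which SLR1 is removed when GA binds GID1. Embryoless half-seeds of WT, gid1, gid2 and slr1 were treated for 36 h with 10 µM GA or mock-treated, and GA was compared with mock on 4 arrays per genotype, which give 2 replicates each.

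Signal differed between genotypes, each of which lay on its own slide. Median Cy3 intensity was 195 to 286 on the WT arrays, 390 to 511 on those labelled gid1, 297 to 506 on those of gid2 and 47.4 to 62.3 on those labelled slr1, which were read on another scanner. Between 68.6% and 77.5% of probes were well above background on the WT arrays, against 54.5% to 68.9% on those labelled slr1. Slide and genotype therefore cannot be told apart for levels, while each GA ratio was measured within an array.

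The transcripts of the pathway itself were examined first. In untreated WT, SLR1 (Os03g0707600) stood at a log2 intensity of 12.93, with 13.04 on the arrays labelled gid1 and 12.93 on those of gid2. On the arrays labelled slr1 it stood at 11.19, lower than WT by a log2 difference of −1.74 ± 0.20 (SE, n = 2 against 2; limma adjusted p = 8.58e-04), which is at the 2.23rd percentile of such differences over all genes. It was still well above background there. GID1 (Os05g0407500) was at 9.60 in untreated WT and 10.43 on the arrays labelled gid1, a difference of 0.82 ± 0.21 that did not pass the test (limma adjusted p = 0.0964). The labels do not give the mutations, and a transcript level checks nothing for a point mutation or a probe outside a deletion. The locus given for GID2 (Os02g0580300), described on the array as a 14-3-3-like protein, stood at 12.42 in untreated WT and 12.21 in untreated gid2.

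GA reshaped the WT transcriptome. The largest rises were in alpha-amylases, the enzymes that break down starch: isozyme 3B (Os09g0457600) rose by 7.82 ± 1.11 on the log2 scale (SE, n = 2; 226-fold; limma adjusted p = 0.00178) and isozyme 1B (Os02g0765400) by 6.76 ± 0.63 (109-fold; limma adjusted p = 3.87e-04). The largest falls were in genes of the dry, dormant seed: globulin 2 (Os03g0793700), a storage protein, changed by −6.56 ± 0.66, and 1-Cys peroxiredoxin (Os07g0638300), an antioxidant of dormant seeds, by −6.07 ± 0.34, saturated in the mock channel of 2 arrays, so that its fall is understated there. In all, 5061 genes rose and 5610 fell of 21798 tested (limma), and 1112 and 1557 of these changed at least 2-fold. Both replicates moved together, with r = 0.952 across genes, which are not independent replicates. Without WT replicate 2, 4991 genes passed.

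Of the 9 alpha-amylases, 6 rose and 3 fell in WT. Isozyme 3C (Os09g0457800) rose by 4.75 ± 0.61, Os02g0765600 by 3.47 ± 0.26 and Os02g0765300 by 3.0 ± 0.56. The array describes Os02g0765600 and Os02g0765300 as isozyme 1B too, so its descriptions do not tell them apart from Os02g0765400. In this text isozyme 1B stands only for Os02g0765400. Os08g0473600 rose by 2.73 ± 0.91, saturated in the GA channel of 2 arrays, so that its rise is understated there. Os09g0457400, Os08g0473900 and Os04g0403300 fell, with log2 ratios of −4.87 ± 1.02, −3.90 ± 0.42 and −0.95 ± 0.09. None of the 6 other starch-degrading enzymes passed. camera did not call the alpha-amylases (adjusted p = 0.210), and fry, which tests whether members move one way on balance, did (adjusted p = 0.0357).

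**Figure D1:**
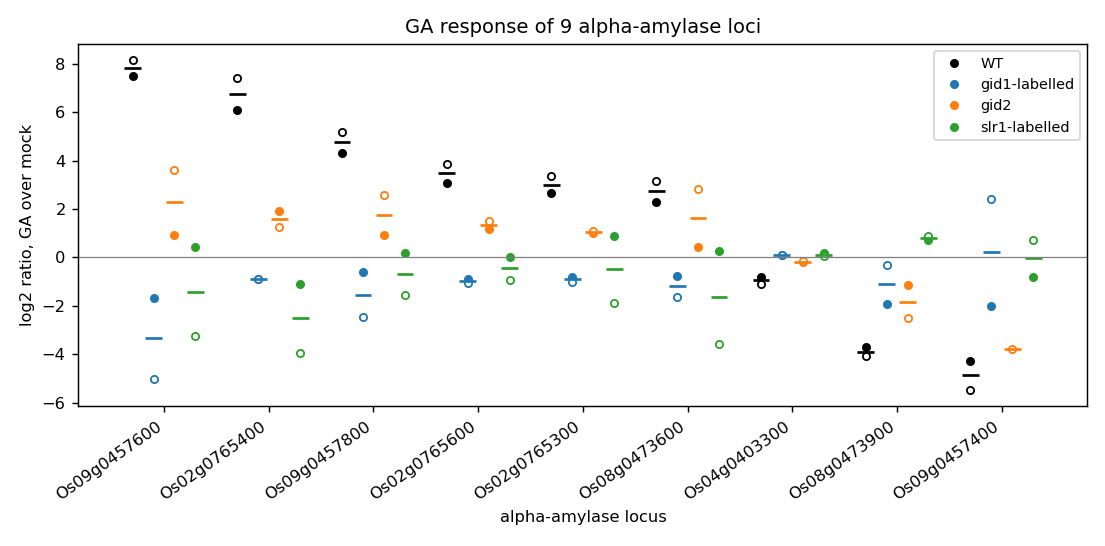
GA over mock log2 ratio (y axis) of each of the 9 alpha-amylase loci (x axis), by genotype. Filled points are replicate 1, open points replicate 2 and bars their mean (a single value where the other is missing); WT reaches 7.82 for Os09g0457600, while points of the arrays labelled gid1 lie below 0 for the 6 loci that rose in WT.

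The lists that camera called upward were cysteine proteinases, the secretory machinery, phosphatases and ribosomal proteins. Of 16 cysteine proteinases, which digest storage protein, 9 rose and 3 fell, with oryzain gamma (Os09g0442300) at 1.78 ± 0.14 and cysteine proteinase 1 (Os04g0311400) at 0.99 ± 0.09. Of 41 genes of endoplasmic reticulum folding and secretion, 26 rose and 5 fell. Among them the endosperm lumenal binding protein (Os02g0115900), a chaperone of the reticulum, rose by 3.39 ± 0.24, and SEC61 beta (Os01g0565900), part of the channel through which secreted proteins enter, by 1.62 ± 0.10. Of 19 phosphatases and phosphate transporters 13 rose and 1 fell, including the purple acid phosphatases Os03g0238600 (2.78 ± 0.29) and Os11g0151800 (1.08 ± 0.10). Of 147 cytosolic ribosomal proteins 61 rose and 20 fell; S14 (Os02g0534800) rose by 0.99 ± 0.07, and L10a-3 (Os08g0558000) had a ratio of −1.29 ± 0.11. Adjusted over the list alone, the counts were 27 and 7 for the reticulum list, 14 and 1 for the phosphatases, 63 and 20 for the ribosomal proteins, and as above for the cysteine proteinases. camera called these 4 lists upward, at adjusted p = 7.95e-04 for the reticulum, 7.93e-04 for the phosphatases, 0.00138 for the ribosomal proteins and 0.0296 for the cysteine proteinases. None held once correlation was estimated, with adjusted p = 0.728 with an estimated correlation for the first, second and last and adjusted p = 0.904 with an estimated correlation for the ribosomal proteins.

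Most genes of desiccated seeds and oil bodies fell. Of 30 LEA proteins and dehydrins, which protect desiccated cells, 22 fell and 2 rose, over all genes and adjusted over the list alone, with a median log2 ratio of −1.87. Examples are Os01g0705200 (−5.49 ± 0.36), dehydrin 9 (Os11g0451700, −5.46 ± 0.76), dehydrin RAB25 (Os01g0702500, −5.20 ± 0.40), Os02g0250600 (−5.23 ± 0.35), Os05g0542500 (−5.09 ± 0.41) and Os03g0168100 (−3.80 ± 0.25). camera called the list downward (adjusted p = 8.74e-05), with adjusted p = 0.728 with an estimated correlation. Of 10 markers of embryo and oil bodies 7 fell and 1 rose, 7 and 2 adjusted over the list alone. Oleosin Os09g0324000, a coat protein of oil bodies, fell by 5.09 ± 0.21 on the log2 scale, and oleosin Os05g0576700 fell by 2.12 ± 0.11. This list was called by fry (adjusted p = 0.00105) and not by camera (adjusted p = 0.0747). A dormancy-associated protein (Os11g0671000, −5.45 ± 0.19) and a cupin (Os03g0336100, −5.38 ± 0.57) were also among the 10 largest falls.

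Hormone genes moved both ways. In gibberellin metabolism 6 of 13 genes fell and 3 rose, among them a GA 20-oxidase (Os01g0883800, −1.70 ± 0.17), which makes GA precursors, and a GA 2-oxidase (Os01g0209700, −1.60 ± 0.12), which inactivates GA. GID1 fell by 1.31 ± 0.17 (limma adjusted p = 0.00138) and GAMYB (Os01g0812000, MYB8 on the array), a transcriptional activator of alpha-amylase genes, rose by 0.79 ± 0.16 (limma adjusted p = 0.00685), so that of the 3 signalling genes 1 rose and 1 fell. SLR1 had a ratio of 0.19 ± 0.09 and the GID2 locus 0.11 ± 0.09, which did not pass (limma adjusted p = 0.128 and 0.357). Of 71 abscisic acid response genes 18 rose and 22 fell, 18 and 23 adjusted over the list alone, with a protein phosphatase 2C (Os09g0325700) at −3.72 ± 0.19 and an HVA22-like gene (Os02g0747500) at 1.57 ± 0.08. Counts adjusted over the list alone were 3 and 6 for metabolism and 1 and 1 for signalling.

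Transport, defence and antioxidant genes moved both ways, and camera called none of these lists (smallest adjusted p = 0.231). fry called sugar transporters (adjusted p = 0.00969), amino acid and peptide transporters (0.00576) and defence proteins (0.0358) downward. Among 29 sugar transporters 13 fell and 3 rose (15 and 4 adjusted over the list alone), with Os04g0453400 at −1.54 ± 0.13 and Os10g0579200 at 1.38 ± 0.12. Among 32 amino acid and peptide transporters 11 fell and 9 rose, with amino acid permease 6 (Os07g0134000) at −3.47 ± 0.12 and Os06g0706400 at −2.48 ± 0.10. Among 7 aquaporins 3 rose and 2 fell: a plasma membrane form (Os04g0521100) rose by 3.49 ± 0.33, measured above background in 1 of 4 mock channels, and a tonoplast form (Os04g0527900) had a ratio of −3.07 ± 0.22. Among 73 defence proteins 20 fell and 4 rose (19 and 4 adjusted over the list alone), including the chitinases Os08g0518800 (−1.98 ± 0.10) and Os11g0702100 (−1.96 ± 0.13). Among 45 antioxidant genes 15 fell and 10 rose, a metallothionein (Os11g0704500) rising by 1.60 ± 0.13. Counts adjusted over the list alone were the same for the amino acid transporters, aquaporins and antioxidant genes.

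Most of the other lists also held both members that rose and members that fell. Of 50 serine carboxypeptidases and aspartic proteinases 15 rose and 11 fell, the pepsin-family peptidases Os02g0314600 and Os12g0177500 moving by 1.91 ± 0.14 and −1.06 ± 0.07. Of 75 cell wall genes 25 rose and 14 fell, and the members of lowest p both fell: a xyloglucan endotransglucosylase (Os06g0697000, −4.86 ± 0.23) and a beta-1,3-glucanase (Os03g0669300, −2.63 ± 0.11). Of 5 nucleases 2 rose, a bifunctional nuclease (Os01g0128200) by 2.57 ± 0.21 and ribonuclease 2 (Os01g0897200) by 0.31 ± 0.06. Of 15 genes of fatty acid oxidation and the glyoxylate cycle 6 rose and 4 fell (6 and 5 adjusted over the list alone). Glyoxysomal malate dehydrogenase (Os03g0773800) was at −0.92 ± 0.07. A gene described only as of the isocitrate lyase and phosphorylmutase family (Os04g0386600) was at −1.76 ± 0.13. Of 52 heat shock proteins 11 rose and 11 fell, with HSP82 (Os09g0482100) at −1.62 ± 0.08 and HSP70 (Os11g0703900) at −1.98 ± 0.09. Of 42 histones and cyclins 9 rose and 7 fell (8 and 6 adjusted over the list alone), with histone H3 (Os01g0866200) at 2.23 ± 0.22 and H2A.2.1 (Os05g0461400) at −0.77 ± 0.07. Of 11 genes of autophagy and vacuolar processing 4 rose and 4 fell; Apg6 (Os03g0644000) rose by 1.1 ± 0.08 and a vacuolar processing enzyme (Os01g0559600) by 1.08 ± 0.12. Counts adjusted over the list alone were as over all genes where not given.

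Markers of other tissues were measured in the same way. Of 45 starchy endosperm markers 2 fell and 1 rose (2 and 0 adjusted over the list alone), the falls being a granule-bound starch synthase (Os10g0437600, −1.21 ± 0.16) and an ADP-glucose pyrophosphorylase large subunit (Os05g0580000, −1.87 ± 0.30). Of 23 photosynthesis genes 6 fell and 3 rose (6 and 2 adjusted over the list alone), with a photosystem II W protein (Os01g0773700) at −2.85 ± 0.24 and a photosystem I subunit (Os05g0560000) at −2.40 ± 0.20. Over the 25 lists in WT, camera called 5 and fry 13 in one direction, and no camera call held with an estimated correlation (smallest adjusted p = 0.728). fry's calls were upward for alpha-amylases, cysteine proteinases, nucleases, phosphatases and reticulum genes. They were downward for sugar and amino acid transporters, gibberellin metabolism, LEA proteins, abscisic acid response, defence proteins, embryo markers and photosynthesis genes. fry's mixed p, for change in either direction, passed in 23 lists, all but other starch-degrading enzymes and starchy endosperm markers (adjusted p = 0.437 and 0.392). Over all genes 49.0% were called in WT, so passing the mixed test says little about any 1 list. Called less often than that were defence proteins, heat shock proteins, nucleases, histones and cyclins, photosynthesis genes, other starch-degrading enzymes and starchy endosperm markers. Median and mean differed in sign in 7 lists: other starch-degrading enzymes, nucleases, fatty acid oxidation, amino acid transporters, gibberellin signalling, heat shock proteins and autophagy. camera's direction was up for these except the amino acid transporters.

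Further large rises in WT were a GDSL lipolytic enzyme (Os02g0740400, 5.91 ± 0.63), a metallophosphoesterase (Os01g0800500, 5.88 ± 0.59), a nodulin 21-like gene (Os04g0538400, 5.83 ± 0.73) and a DSBA oxidoreductase (Os04g0227500, 5.39 ± 0.55). A gene described as MYST1 (Os12g0131900) rose by 4.78 ± 0.60, a NAM/CUC2-like transcription factor gene (Os04g0515900) by 4.59 ± 0.37 and a laccase (Os01g0842500), above background in 2 of 4 mock channels, by 4.59 ± 0.43.

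On the arrays labelled gid1, the question was whether any GA response remains without the receptor. Alpha-amylase ratios lay below 0 for all 6 members that rose in WT: isozyme 3B was at −3.35 ± 1.11, isozyme 1B (Os02g0765400) at −0.89 ± 0.63 and Os02g0765600 at −0.99 ± 0.26, and none passed (limma adjusted p = 0.636, 0.869 and 0.582). No gene of 21817 passed (limma), 1494 had an unadjusted p under 0.05 and the smallest adjusted p was 0.151. The replicates opposed each other (r = −0.300 across genes), although arrays of the same number and opposite dye correlated at 0.750 to 0.816. The genes that fell in WT by at least 2-fold had a median of −0.21 in replicate 1 and 0.21 in replicate 2.

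camera nevertheless called 6 of the 25 lists there: alpha-amylases (median −0.99; adjusted p = 0.00115), phosphatases (median −0.13; 0.0103), defence proteins (median −0.10; 0.0214) and heat shock proteins (median −0.13; 1.57e-04) downward, ribosomal proteins (median 0.06; 0.00115) and histones and cyclins (median 0.10; 1.57e-04) upward. All had adjusted p = 0.878 with an estimated correlation, and fry called none in one direction (smallest adjusted p = 0.476). fry's mixed p passed for 1 list, the serine carboxypeptidases and aspartic proteinases (adjusted p = 0.00742). Adjusted over the list alone, 1 heat shock protein rose and 1 fell, 1 cysteine proteinase and 2 serine carboxypeptidases or aspartic proteinases fell, 1 abscisic acid response gene rose, and no member of the other lists passed. Median and mean differed in sign for other starch-degrading enzymes, fatty acid oxidation, gibberellin metabolism and embryo markers, where camera followed the mean. Counts depended on the replicates: 345 genes passed without the second replicate, 760 with the 4 arrays taken as separate samples and 490 with the second replicate's ratios turned, a setting chosen after seeing the data.

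In gid2, a smaller set of genes changed. Os02g0765600, an alpha-amylase, rose by 1.35 ± 0.26 (limma adjusted p = 0.0474). It was the 1 member of its list to pass (1 rose and 1 fell adjusted over the list alone), although the others that rose in WT lay between 1.04 and 2.27. A bicarbonate transporter-like gene (Os12g0566000) rose by 1.81 ± 0.33, a UDP-glycosyltransferase (Os04g0525100) by 1.74 ± 0.16, a potassium channel (Os06g0250600) by 1.51 ± 0.25 and a TGF-beta receptor-like gene (Os01g0902700) by 1.41 ± 0.26. Of these the last had a WT ratio of −0.28 ± 0.26, and the others rose in WT too. The largest falls were in a family 18 glycoside hydrolase (Os05g0247100, −2.40 ± 0.37), the lignin pathway enzymes cinnamyl-alcohol dehydrogenase (Os02g0187800, −2.28 ± 0.34) and cinnamoyl-CoA reductase (Os08g0441500, −2.09 ± 0.39), a lipid transfer or inhibitor protein (Os03g0103300, −2.22 ± 0.34) and a peroxidase (Os07g0677100, −2.13 ± 0.33). These 5 also fell in WT.

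In total 420 genes rose and 626 fell of 21792 in gid2 (limma; 6544 at an unadjusted p under 0.05), 39 and 142 by at least 2-fold. Replicates correlated at 0.765 across genes. Of the 419 that rose and were tested in both, 191 also rose in WT (97.4 from independent lists) and 51 fell there. Of the 626 that fell, 475 also fell in WT (161 from independent lists) and 13 rose. Both lists share 1 estimate of the spread of each gene, so genes of small spread can pass in both. The lists are thus not independent, and the overlap was not tested against those values. The count depended on the setting, downward and upward: none passed with the software's processed intensities, with the value table, without the arrays labelled slr1 (a setting chosen after seeing the data) or without gid2 replicate 2, and 1 without gid2 replicate 1. None passed with a replicate block either, although the replicate numbers did not pair the samples. With median centring in place of loess 26 rose and 79 fell, and 608 genes passed with the filter over all arrays and 619 without background subtraction. More passed with only the genotypes compared (2600), without the arrays labelled gid1 (3701, chosen after seeing the data), with duplicateCorrelation (4283) and with the arrays as separate samples (8220).

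Among the lists in gid2, camera called the LEA proteins and dehydrins downward (median −0.70, 2 of 30 fell, 4 adjusted over the list alone; adjusted p = 0.00246, and adjusted p = 0.926 with an estimated correlation). fry called the abscisic acid response downward (1 rose and 5 fell of 71, the same adjusted over the list alone; adjusted p = 0.0423). Its mixed p passed in 16 lists, with adjusted p = 0.00126 for cell wall genes and for defence proteins and 0.00452 for sugar transporters. Over all genes 4.80% were called in gid2, and 6544 of 21792 had an unadjusted p under 0.05 (limma). These mixed calls therefore say little about any 1 list. Cell wall genes fell in 6 of 75 cases (6 fell and 1 rose adjusted over the list alone), defence proteins in 5 of 73 with 1 rise (9 and 3 adjusted over the list alone), amino acid transporters in 3 of 32 (4 adjusted over the list alone) and sugar transporters in 2 of 29 (5, and 2 rises, adjusted over the list alone). The other lists had at most 2 members past the threshold over all genes and at most 5 adjusted over the list alone. Median and mean differed in sign for cell wall genes, aquaporins, gibberellin metabolism and green tissue markers, where camera followed the mean except for aquaporins. GID1 was at −0.19 ± 0.17 and GAMYB at 0.30 ± 0.16 in gid2, which did not pass (limma adjusted p = 0.489 and 0.251).

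On the arrays labelled slr1, where the offset draws ratios of dim genes toward 0, GA added no detected change. Isozyme 1B (Os02g0765400) was at −2.52 ± 0.63 and isozyme 3B at −1.42 ± 1.11, with limma adjusted p = 1 for both, and replicates of isozyme 3B stood at 0.41 and −3.26. No gene of 21856 passed (limma), 575 had an unadjusted p under 0.05, and the smallest adjusted p was 0.452. Replicates did not correlate (r = 0.0312 across genes), while arrays of the same number correlated at 0.400 to 0.617. With the processed intensities 20 genes passed and with the arrays as separate samples 85.

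camera called 9 lists on these arrays, none with an estimated correlation. Starchy endosperm markers lay lower (median −0.45; adjusted p = 5.41e-11), as did phosphatases (−0.23; 5.24e-04), reticulum genes (−0.06; 0.0175), alpha-amylases (−0.49; 0.0281), other starch-degrading enzymes (−0.20; 0.0281) and cell wall genes (−0.05; 0.0298). Heat shock proteins (median 0.09; 5.43e-07), histones and cyclins (0.04; 0.00636) and autophagy (0.07; 0.0281) lay higher. These had adjusted p = 0.464 with an estimated correlation for heat shock proteins and adjusted p = 0.623 with an estimated correlation for the others, and fry called none in one direction (smallest adjusted p = 0.803) or in either. Adjusted over the list alone, 1 heat shock protein and 1 LEA protein rose. Median and mean differed in sign for sugar transporters, abscisic acid response and antioxidant genes, where camera followed the mean except for abscisic acid response.

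The differences in response were tested directly. Alpha-amylase isozyme 3B responded more in WT by a log2 difference of 11.17 ± 1.57 against the arrays labelled gid1, 5.55 ± 1.57 against gid2 and 9.24 ± 1.57 against those labelled slr1 (limma adjusted p = 0.00328, 0.0436 and 0.00644). For isozyme 1B (Os02g0765400) the differences were 7.65 ± 0.89, 5.18 ± 0.89 and 9.28 ± 0.89. The dormancy-associated gene Os11g0671000 fell more in WT, with differences of −5.33 ± 0.27, −5.18 ± 0.27 and −5.73 ± 0.27. Between WT and the arrays labelled gid1, 3784 genes responded higher and 4260 lower in WT (8044 of 21786, limma). Between WT and gid2 the counts were 2664 and 3061 (5725 of 21774), and between WT and the arrays labelled slr1 3406 and 4010 (7416 of 21798). The last pair of counts carries the limit of the offset on dim arrays. Without WT replicate 2 the totals were 3594, 1602 and 3256; without gid2 replicate 1 or 2 that against gid2 was 1509 or 2223, and without slr1 replicate 1 or 2 that against slr1 was 4072 or 3730.

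Other genes with the largest differences from all 3 mutants were the lipolytic enzyme Os02g0740400 (7.87 ± 0.89, 5.04 ± 0.89 and 7.02 ± 0.89 against gid1, gid2 and slr1), the metallophosphoesterase Os01g0800500 (7.05 ± 0.83, 5.33 ± 0.83 and 6.80 ± 0.83), globulin 2 (Os03g0793700; −6.10 ± 0.93, −4.85 ± 0.93 and −6.62 ± 0.93) and 1-Cys peroxiredoxin (Os07g0638300; −6.08 ± 0.48, −4.90 ± 0.48 and −6.20 ± 0.48). The last was saturated in 2 mock channels of WT, in 2 of gid2 and in 1 GA and 1 mock channel of the arrays labelled gid1, so its differences are not exact. On the arrays labelled slr1 the metallophosphoesterase was well above background in only 1 of 4 GA and 2 of 4 mock channels. Its difference from slr1 is not exact either. LEA gene Os01g0705200 differed by −5.37 ± 0.50 from gid1 and −5.60 ± 0.50 from slr1, LEA gene Os02g0250600 by −5.19 ± 0.49 from gid1 and −4.54 ± 0.49 from gid2, and dehydrin 9 (Os11g0451700) by −5.77 ± 1.08 from slr1. The nodulin 21-like gene Os04g0538400 differed by 4.94 ± 1.04 from gid2 and 7.18 ± 1.04 from slr1, isozyme 3C (Os09g0457800) by 6.30 ± 0.87 from gid1, and catalase A (Os02g0115700), which fell by 3.93 ± 0.59 in WT and was at 0.58 ± 0.59 in gid2, by −4.50 ± 0.84.

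Group by group, reticulum genes responded more in WT than on the arrays labelled gid1 in 22 of 41 cases, than in gid2 in 22 and than on those labelled slr1 in 23. LEA proteins and dehydrins responded lower in WT in 18, 13 and 19 of 30 cases, and phosphatases higher in 12, 8 and 11 of 19. Adjusted over the list alone these were 24, 24 and 25, then 18, 17 and 20, and 14, 10 and 15. camera called reticulum genes, phosphatases and LEA proteins in all 3 differences, at adjusted p = 3.41e-04, 2.59e-04 and 1.40e-04 for the reticulum genes, 2.77e-04, 0.00151 and 9.40e-05 for the phosphatases and 6.31e-05, 0.00134 and 4.38e-05 for the LEA proteins. No list of the 25 was called with an estimated correlation: LEA proteins had adjusted p = 0.706, 0.860 and 0.683 with an estimated correlation, and the others adjusted p = 0.686, 0.772 and 0.603 with an estimated correlation. camera also called cysteine proteinases against gid1 and slr1 (adjusted p = 0.0415 and 0.0235, with adjusted p = 0.686 and 0.603 with an estimated correlation) and ribosomal proteins against gid2 and slr1 (0.0444 and 0.00230, with adjusted p = 0.966 and 0.874 with an estimated correlation). fry called 13, 8 and 12 lists in one direction and 22 in either direction in each difference. Over all genes 36.9%, 26.3% and 34.0% were called, so the calls in either direction say little about any 1 list. Lists with directional calls in all 3 differences were cysteine proteinases, phosphatases and reticulum genes upward and gibberellin metabolism, LEA proteins and embryo markers downward. Median and mean differed in sign for gibberellin signalling in each difference, for fatty acid oxidation and autophagy against gid1 and slr1, and for nucleases, aquaporins, amino acid transporters and abscisic acid response against gid2. There camera followed the mean, except for gibberellin signalling against gid2 and slr1 and abscisic acid response against gid2. Against gid1, camera's direction opposed both median and mean for other starch-degrading enzymes (−0.04 and −0.06, up) and histones and cyclins (0.03 and 0.04, down), and neither was called.

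Between mutants, 115 genes had a higher and 104 a lower ratio on the arrays labelled gid1 than in gid2 (limma; 219 of 21785, and 5533 at an unadjusted p under 0.05). The count was 6740 with the arrays as separate samples, 3038 with duplicateCorrelation and 711 with the trend and robust moderation, and none passed with a replicate block. No gene passed with the processed intensities, with only the genotypes compared, without either gid2 replicate or without the arrays labelled slr1 (chosen after seeing the data), 2844 passed without gid1 replicate 1, and median centring left 23 and 10. No gene passed between the arrays labelled gid1 and slr1 (limma; 702 at an unadjusted p under 0.05) or between gid2 and those labelled slr1 (limma; 4383 at an unadjusted p under 0.05), with smallest adjusted p = 0.630 and 0.0966. These counts of 0 depended on the setting too. Between gid1 and slr1, 73 genes passed with the arrays as separate samples, 80 without gid1 replicate 2 and 125 with that replicate turned (chosen after seeing the data). Between gid2 and slr1, 633 passed with only the genotypes compared, 820 without the arrays labelled gid1 (chosen after seeing the data), 1638 with duplicateCorrelation and 5099 with the arrays as separate samples.

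The genes called in WT were then followed as 2 sets. In WT, by which the sets were chosen, the 5061 that rose had replicate medians of 0.50 and 0.66, and in gid2 of 0.10 and 0.14. The 5610 that fell had −0.54 and −0.71 in WT and −0.13 and −0.19 in gid2. On the arrays labelled gid1 the medians were −0.02 and −0.06 for the first set and −0.03 and 0.08 for the second, and on those labelled slr1 0.00 and −0.04, and 0.02 and 0.02. Slopes on the WT response were 0.180 and 0.281 in gid2, 0.0605 and −0.128 for gid1 and −0.00467 and −0.0700 for slr1. camera called the first set upward in gid2 (adjusted p = 7.02e-12) and the second downward (4.20e-16), both with adjusted p = 0.149 with an estimated correlation; fry gave adjusted p = 0.0596 for both, and 9.12e-04 for change in either direction. It called the first set downward and the second upward on the arrays labelled gid1 (adjusted p = 9.49e-05 and 0.0279; both adjusted p = 0.608 with an estimated correlation) and slr1 (0.00274 and 0.0352; both adjusted p = 0.622 with an estimated correlation). No set test is given for the differences from WT, because the sets were chosen on the WT response that enters them. With the value table as labelled, the first set's median for gid1 was 0.05, but its gid1 columns follow the scanner files labelled slr1. With median centring the medians for slr1 were 0.18 and 0.15.

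**Figure D2:**
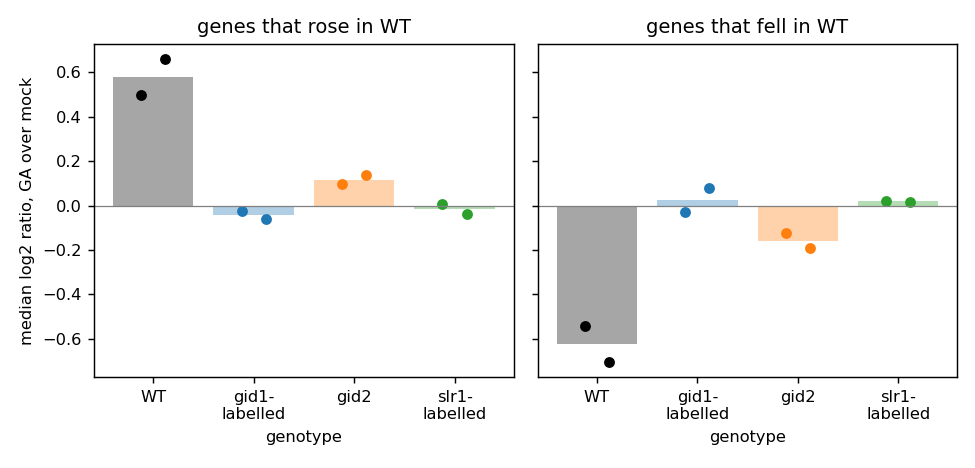
Median GA over mock log2 ratio (y axis) of the 5061 genes that rose and the 5610 that fell in WT, by genotype (x axis); points are the 2 replicates and bars their mean. Medians in gid2 lie at 0.10 and 0.14 and at −0.13 and −0.19, on WT's side of 0 in both replicates.

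**Figure D3:**
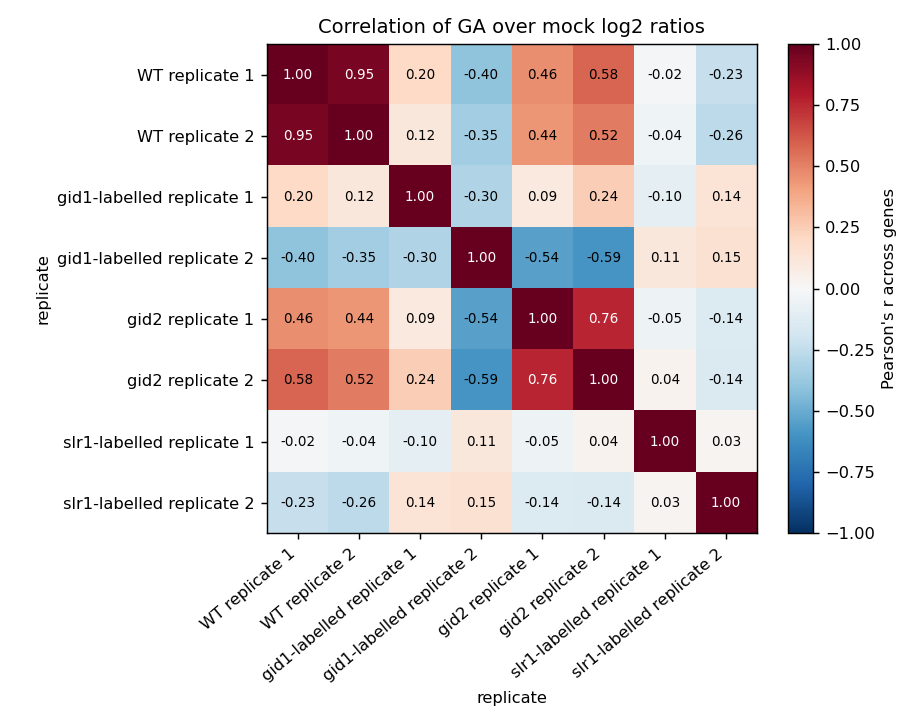
Pearson's r across genes (colour, from −1 to 1) between the GA over mock log2 ratios of the 8 replicates, listed on both axes by genotype and replicate. The 2 WT replicates stand at 0.95, and those labelled gid1 at −0.30.

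Levels without GA were compared last, to ask whether untreated mutants sit nearer to untreated or to GA-treated WT. On the untreated arrays labelled slr1, isozyme 3B was higher than in untreated WT by 4.72 ± 1.55 on the log2 scale (limma adjusted p = 0.0392), isozyme 1B (Os02g0765400) by 4.32 ± 0.90 and Os02g0765600 by 2.54 ± 0.27. The dormancy-associated gene Os11g0671000 differed by −4.28 ± 0.17, LEA gene Os01g0705200 by −3.53 ± 0.28 and globulin 2 by −3.57 ± 0.61. The higher amylase levels were not particular to these arrays. Against 10.56, 11.60 and 14.35 in untreated WT, the same amylases stood at 12.59, 13.37 and 16.63 on the untreated arrays labelled gid1. In untreated gid2 they stood at 11.24, 13.26 and 15.55. The dormancy-associated, LEA and globulin genes stayed nearer to untreated WT (16.76, 16.73 and 16.89), at 16.26, 16.24 and 16.27 for gid1 and 16.25, 16.64 and 16.37 for gid2. Lower on the untreated arrays labelled slr1 too were GA 20-oxidase Os01g0883800 (−1.53 ± 0.18), GA 2-oxidase Os01g0209700 (−1.85 ± 0.14) and GID1 (−0.78 ± 0.21), which all fell with GA in WT. The GA 2-oxidase was well above background in only 2 of 4 mock channels there, so its difference is not exact. In total 4976 genes were higher and 5999 lower of 21798 (limma). The set that rose in WT had a mean median of 0.20 (0.15 and 0.25 by replicate; 0.58 with GA in WT), and the set that fell had −0.47 in both replicates (−0.63 with GA in WT). With the processed intensities these medians were 0.33 and −0.71. The slope on the WT response was 0.492.

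Part of such a slope comes from the shared untreated WT arrays: a simulated unchanged group gave 0.0137, with a covariance of 0.0169 against 0.597 observed. With the WT replicates split, so that the 2 sides shared none, the slopes were 0.547 and 0.373. They cover 2249 and 3273 genes, against 10605 for the slope of 0.492. On the untreated arrays labelled gid1, 82 genes were higher and 81 lower of 21786 (limma; slope 0.0331), among them Os02g0765600 at 2.28 ± 0.27 (limma adjusted p = 0.0294). No gene of 21774 passed in untreated gid2 (limma; 1720 at an unadjusted p under 0.05; slope −0.0151). For gid1, 5 genes passed without WT replicate 1 or without WT replicate 2, and 2 without gid1 replicate 2. Each of these comparisons is also one between slides, and for slr1 between scanners.

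Gene groups on the untreated arrays labelled slr1 are to be read against all genes, of which 4976 of 21798 were higher and 5999 lower. Lists near or under that share show nothing particular to the list. Among these are serine carboxypeptidases and aspartic proteinases, defence proteins and ribosomal proteins. LEA proteins and dehydrins were lower in 15 of 30 cases and higher in 6 (median −0.87), photosynthesis genes lower in 13 of 23 and higher in 4 (median −0.60), and heat shock proteins higher in 21 of 52 and lower in 13 (median 0.37). Alpha-amylases were higher in 3 and lower in 3 (median 0.13), cysteine proteinases higher in 5 and lower in 4 (median −0.10), reticulum genes higher in 11 and lower in 6 (median 0.06) and ribosomal proteins higher in 20 and lower in 26 (median −0.0024). Phosphatases were higher in 6 and lower in 4 (median 0.47), other starch-degrading enzymes in 3 and 0, cell wall genes in 21 and 15, histones and cyclins in 13 and 9, autophagy genes in 4 and 2 and nucleases in 1 and 1. More were lower than higher among serine carboxypeptidases and aspartic proteinases (15 against 10), fatty acid oxidation (7 against 2), aquaporins (3 against 1), sugar transporters (11 against 4) and amino acid transporters (13 against 6). The same held for gibberellin metabolism (6 against 3), gibberellin signalling (2 against 0), abscisic acid response (27 against 18), defence proteins (21 against 16), antioxidant genes (15 against 8) and embryo markers (3 against 2). Starchy endosperm markers were higher in 15 of 45 cases and lower in 1 (median 0.51), whereas the medians of these markers were −0.71 on the arrays labelled gid1 and −0.74 in gid2, with no member past the threshold (limma).

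**Figure D4:**
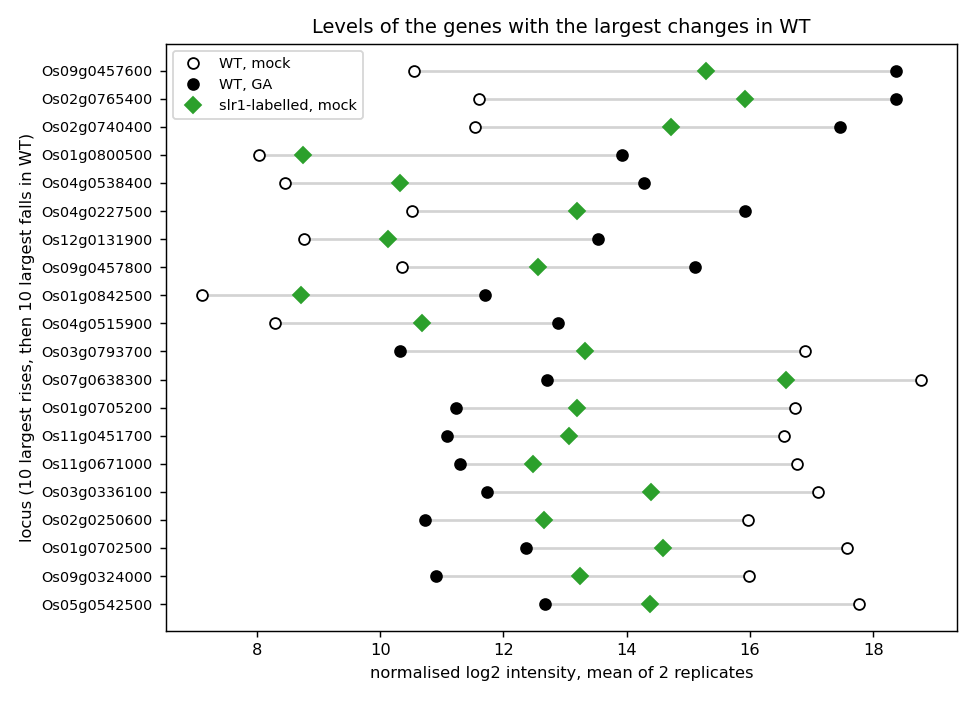
Normalised log2 intensity (x axis, mean of 2 replicates) of the 10 genes with the largest rises and the 10 with the largest falls in WT (y axis). The other untreated mutants are not drawn. Open circles are mock-treated WT, filled circles GA-treated WT and diamonds the mock-treated arrays labelled slr1, as for isozyme 3B (Os09g0457600) at 10.56, 18.37 and 15.28; Os07g0638300 was saturated on 2 mock-treated WT arrays.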

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

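Of the tests in this part, only that of brightness on the arrays labelled slr1 had its outcome bounds set before its result was seen, and the other tests were chosen after related values had been seen.

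Responses of some genotypes differed by a test of the difference itself. Between WT and the arrays labelled gid1 8044 genes differed, between WT and gid2 5725, between WT and the arrays labelled slr1 7416, and between gid1 and gid2 219 (limma). The last count was 0 without either gid2 replicate, with the processed intensities and with only the genotypes compared. Between gid1 and slr1 and between gid2 and slr1 no gene passed (limma; 702 and 4383 at an unadjusted p under 0.05), although 73 and 5099 did with the arrays as separate samples.

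Some arrays stood apart from the other 3 of their genotype by Dixon's test. The WT array of replicate 1 with GA in Cy5 had a log2 ratio SD of 0.598 against 0.877 to 0.895, a median of 0.38 for the genes that rose in WT against 0.63 to 0.67, and a median of −0.34 for those that fell against −0.76 to −0.71. The array labelled slr1 of replicate 1 with GA in Cy3 had an SD of 0.170 against 0.237 to 0.25. Of 20 groups tested 4 passed, 3 of them on the 1 WT array, and chance gives about 1 in 20.

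The array also carries 510 microRNA probes, which were not used in any comparison. A median of 18.8% of them were well above background (2.94% to 31.3% over arrays and channels), against 1.31% of negative control spots (0% to 9.15%) and 74.1% of gene probes.

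The value table and the scanner files give gid1 and slr1 to each other's arrays, so 1 of these sources has labels exchanged. An exchange among the scanner files would put the slr1 mutant on the arrays labelled gid1. Their untreated levels had a slope of 0.0331 on the WT response (0.0814 and −0.0226 with the WT replicates split), which argues against it. The untreated arrays labelled slr1 had a slope of 0.492 (0.547 and 0.373 split), and their SLR1 transcript stood at 11.19 against 13.04 on those labelled gid1 and 12.93 in WT, so that an exchange of columns in the value table is a candidate explanation. Both readings assume that slr1 lacks a working repressor, which the labels do not state, and that this stands in for GA, a transcript level need not follow a mutation, and each genotype lies on its own slide.

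The untreated arrays labelled slr1 lay toward GA-treated WT. Compression of signal on their dimmer slide would follow a gene's brightness. Yet over the genes called in WT the slope was 0.467 with brightness removed first and 0.483 with brightness fitted jointly. With the WT replicates split, the joint slopes were 0.547 and 0.365, over genes changed at least 2-fold in 1 WT replicate. These slopes argue against compression as the whole cause. Other differences between slides and scanners stay open and cannot be told apart from genotype. Loss of the repressor may give the same shift, as an untested hypothesis.

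The replicates labelled gid1 opposed each other, while those of gid2 followed WT weakly. A dye or single-array effect is argued against by the lowest correlation of same-numbered gid1 arrays of opposite dye, 0.750. GA and mock exchanged in the second gid1 replicate stays open: once turned, it correlated with the first at 0.265 over genes changed 2-fold in WT, between the bounds set. Variation between RNA samples unrelated to GA could also give these slopes, since the smaller gid2 slope was 0.180 against a largest size of 0.128 in the other mutants, and an exact test of 2 against 4 replicates cannot go below 0.0667. A response to GA that persists in gid2 is the biological alternative and was not tested apart from these.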

How the results depend on the processing

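Settings that left out the arrays labelled gid1 or slr1, turned the second gid1 replicate, matched the value table to the scanner files, left out 1 WT array or crossed the pairing were tests chosen after seeing the data. Signal over background limits the comparisons with the arrays labelled slr1, and the number of arrays limits all of them; these limits were not compared with each other. No called change of a named gene turned its sign: of the values under other settings, 1129 of 1135 kept their side of the threshold in WT, 73 of 157 in gid2, 179 of 179 for WT minus gid1, 168 of 189 for WT minus gid2 and 177 of 179 for WT minus slr1. The median for gid1 of the genes that rose in WT was −0.0423, and 0.0501 with the value table as labelled. The table's gid1 columns follow the scanner files labelled slr1. The 2 medians are thus of different arrays and do not show that processing turned the sign. Medians near 0 changed sign under other settings. These were that of the genes that rose for slr1 (−0.0162) with median centring, the matched value table and without slr1 replicate 2, that of the genes that fell for gid1 (0.0249) without gid1 replicate 2, and those of both sets in untreated gid1 and gid2 under some settings. So did the uncalled GID2 in WT without WT replicate 1. Causes were not tested unless the setting itself gives them, such as more probes, fewer samples or a stricter minimum. Where a replicate was left out, the lone replicate was assumed to vary like the other genotypes.

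Counts of genes (limma) moved as follows. With every probe on its own, WT gave 16041, WT minus gid1 12149, WT minus gid2 8791 and WT minus slr1 11349. With a 2-fold minimum they were 2669 in WT, 181 in gid2, 2873, 1853 and 2740 for the same differences and 124 for gid1 minus gid2. With the 4 arrays as separate samples they were 760 in gid1, 8220 in gid2, 85 in slr1, 12302, 10518 and 11906 for the differences from WT, 6740 for gid1 minus gid2, 73 for gid1 minus slr1 and 5099 for gid2 minus slr1. With duplicateCorrelation (consensus 0.539) they were 49 in gid1, 4283 in gid2, 2 in slr1, 3038 for gid1 minus gid2, 5 for gid1 minus slr1 and 1638 for gid2 minus slr1. With median centring they were 26 up and 79 down in gid2 (1.1e+02 in all), 4784, 2615 and 4579 for the differences from WT and 33 for gid1 minus gid2. The processed intensities gave 0 in gid2, 20 in slr1 and 0 for gid1 minus gid2. The value table as labelled gave 2 in gid1, 0 in gid2, 1 for gid1 minus gid2 and 1 for gid1 minus slr1. Matched to the scanner files it gave 0 in gid2, 2 in slr1, 0 for gid1 minus gid2, and 1 each for gid1 minus slr1 and gid2 minus slr1. Here and below, its values as labelled for gid1 come from columns that follow the scanner files labelled slr1, and the reverse. Without background subtraction gid2 gave 619. The filter over all 16 arrays left 608 in gid2 and 40 for gid1 minus gid2. The trend and robust moderation gave 2 in gid1 and 711 for gid1 minus gid2.

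With only the genotypes compared, gid2 gave 2600, WT minus gid1 4398, gid1 minus gid2 0 and gid2 minus slr1 633. Without the arrays labelled gid1, gid2 gave 3701 and gid2 minus slr1 820; without those labelled slr1, gid2 and gid1 minus gid2 gave 0. With the second gid1 replicate turned, gid1 gave 490, gid1 minus gid2 31 and gid1 minus slr1 125. Replicate numbers did not pair the samples: deviations of same-numbered replicates correlated at 0.10 (WT and gid1), −0.02 (WT and gid2), −0.12 (WT and slr1), −0.32 (gid1 and gid2), −0.09 (gid1 and slr1) and −0.12 (gid2 and slr1). With a replicate block, gid2 and gid1 minus gid2 gave 0, WT gave 9998, the differences from WT 7099, 4707 and 6478, and the other counts stayed at 0. Crossing the gid2 numbers gave 119 for gid1 minus gid2.

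Leaving out 1 replicate gave 4991 to 7876 in WT, 0 to 345 in gid1, 0 to 1 in gid2, 0 to 2 in slr1, 3594 to 8016 for WT minus gid1, 1509 to 4437 for WT minus gid2 and 3256 to 6100 for WT minus slr1. Between mutants it gave 0 to 2844 for gid1 minus gid2, 0 to 80 for gid1 minus slr1 and 0 to 2 for gid2 minus slr1. The medians of the genes that rose in WT then ranged from 0.10 to 0.15 in gid2, from −0.07 to −0.02 in gid1 and from −0.04 to 0.01 in slr1. Those of the genes that fell ranged from −0.23 to −0.13 in gid2, from −0.03 to 0.08 in gid1 and from 0.0158 to 0.0245 in slr1. For untreated gid1 the count ranged from 2 to 134 and the first set from −0.0618 to 0.0516, and for untreated slr1 the second set from −0.53 to −0.41.

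Other medians moved too. The set that rose was at 0.17 in gid2 with the processed intensities and with median centring, 0.16 with the value table either way, and 0.27 among genes changed 2-fold in WT. The set that fell was at −0.24 in gid2 with median centring and −0.45 among genes changed 2-fold. For slr1 the set that rose was at 0.18 with median centring, 0.0501 with the matched value table and −0.0885 among genes changed 2-fold; the set that fell was at 0.0599 with the processed intensities, 0.15 with median centring, 0.0255 with the filter over all arrays, 0.0268 with the value table as labelled, and 0.11 with the matched table. For gid1 the set that rose was at −0.12 among genes changed 2-fold, and the set that fell at 0.11 with the value table as labelled. Untreated gid1 gave 43 genes with the processed intensities and 87 with median centring. Untreated slr1 gave a second-set median of −0.51 without background subtraction, −0.71 with the processed intensities, −0.64 with median centring, −0.43 with the filter over all arrays and −0.46 with quantile scaling, and a first-set median of 0.33 with the processed intensities and 0.28 with that filter. The number of lists called by camera was 0 in all 7 comparisons with an estimated correlation; with the value table as labelled it was 2 in gid2, 7 for WT minus gid1 and 7 for WT minus gid2, and with the processed intensities 5 in slr1 and 7 for WT minus gid2.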

Other observations

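The genes in the next paragraphs were chosen after their values were seen, and the tests on them are those of the report. The array describes several loci as ent-kaurene oxidase, and its descriptions do not tell which of them acts in gibberellin synthesis. Of these, Os06g0569500 fell by 2.11 ± 0.26 in WT and by 1.82 ± 0.26 in gid2 on the log2 scale (SE, n = 2, limma adjusted p = 0.00104 and 0.0363). It was at −1.11 ± 0.26 on the arrays labelled slr1 and −0.12 ± 0.26 on those labelled gid1, which did not pass. Of the other loci with this description, Os06g0568600 fell by 1.16 ± 0.29 in WT and was at −1.33 ± 0.29 in gid2, which did not pass (limma adjusted p = 0.0514). Os06g0569900 and Os06g0570100 rose in WT, both by 0.38, and were at 0.04 and 0.03 in gid2. A GA 20-oxidase (Os03g0856700) fell by 0.95 ± 0.11 in WT and was at 0.02 ± 0.11 in gid2.

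Some genes fell in gid2 without a called change in WT. A glutathione S-transferase (GST6, Os09g0367700) fell by 1.87 ± 0.26 in gid2 and was at 0.11 in WT (limma adjusted p = 0.0121 for the difference). A caffeoyl-CoA O-methyltransferase (Os08g0498100), of the lignin pathway, fell by 1.65 ± 0.24 with 0.17 in WT (limma adjusted p = 0.0121 for the difference), a plastocyanin-like gene (Os08g0482700) by 1.62 ± 0.25 with 0.37 in WT (limma adjusted p = 0.0115 for the difference) and an ERF domain gene (Os10g0562900) by 1.45 ± 0.24 with −0.16 in WT (limma adjusted p = 0.0335 for the difference). Counts of gid2 calls depended on both replicates: 0 genes passed without gid2 replicate 2 and 1 without gid2 replicate 1 (limma), against 4052 and 2479 at an unadjusted p under 0.05 without replicates 1 and 2.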
